A study of Arabidopsis thaliana with 7 samples.

How the data were processed

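Root RNA of Arabidopsis thaliana was measured on 7 one-colour Affymetrix ATH1 arrays, each array holding RNA pooled from 20 plants per the labels. The 4 groups were the wild type without dexamethasone (2 arrays), the wild type with dexamethasone (2 arrays), the ANR1-GR line without dexamethasone (2 arrays) and the ANR1-GR line with dexamethasone (1 array, replicate 2). The labels describe 2 biological replicates. Group and replicate number were taken from the label of each sample.

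The deposited values are intensity values, 1 linear signal per probe set and array, with 22810 probe sets. In the deposited table the 2% trimmed mean of the signals was 100.0 on each array, which is the scale the authors gave the values. The software and the method that summarised the probes are not given in the sources used here. The scanner background recorded in the labels ran from 62.9 to 85.2 and the noise from 3.80 to 4.91. The number of arrays limits the precision of every comparison.

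Because the trimmed means were equal, the deposited scale was kept. The 64 control probe sets were left out, and 10218 probe sets with a mean signal over the 7 arrays of at least 50.0 (0.5 of the trimmed mean) were tested. The tests ran on log2(signal + 16), so a log2 difference understates the change of dim probe sets. limma 3.58.1 in R 4.3.3 was used (lmFit and eBayes with a trend on mean signal), and the threshold was a Benjamini-Hochberg adjusted p of 0.05. The line was first compared with the wild type over both treatments, in a model with line and dexamethasone as additive terms. The other 5 comparisons were contrasts in a model with the 4 groups: the line without dexamethasone, dexamethasone in the wild type, dexamethasone in the line, the difference of these responses, and the line with dexamethasone. The group with 1 array was assumed to vary like the others.

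Gene names came from the platform annotation, which paired 13513 probe sets with 1 gene and 503 with several, and did not list 8794. Of the 1-gene probe sets, 13436 matched a RefSeq gene by gene ID. Among the tested probe sets 5307 (51.9%) had 1 gene, for 5293 genes. No gene was named from a probe set with several genes or none, and 379 tested probe sets ended in _s_at or _x_at, which mark probes that can read more than 1 transcript.

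These groups, comparisons, tests, alternatives, the rule for named genes and 21 gene lists (282 genes) were fixed before the data were examined. The rule named ANR1 first. It then named, per comparison, up to 12 genes in each direction past the threshold without overlap between the groups' arrays. Where fewer than 6 probe sets passed, it named up to 5 genes per direction with the smallest p among log2 differences of at least 1, stated as not passing. It also named members of the fixed lists past the threshold and up to 4 members of each list whose set test passed. No tested probe set was paired with ANR1, so ANR1 could not be identified among them. Whether a tested probe set without a gene in the annotation reads ANR1 is not known. Probe sets 263295_at and 257722_at were named after their values were seen.

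Of the 282 listed genes, 34 had a probe set in the annotation and 19 passed the filter, and 0 lists reached the 5 measured genes required for a set test. A further 22 lists of gene families and pathways were therefore drawn up after the annotation was seen and before any test, of which 20 were tested with limma's camera at its preset correlation of 0.01, adjusted over the 20 lists within a comparison. A comparison of replicate 2 (4 arrays) with replicate 1 (3 arrays) was added after the pairing had been checked.

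The replicate numbers come from the labels, and they paired the arrays. The deviation of each array from its group mean correlated across probe sets, with r = 0.621 between wild type without and with dexamethasone, 0.472 between untreated wild type and untreated line, and 0.826 between treated wild type and untreated line. Genes are not independent replicates in these values. Each comparison was fitted without the replicate number and, as an alternative, with it as a block. Other alternatives set in advance were quantile normalization, centring on the median, adding 1 or 64 before the log, other filters, no trend, subsets of arrays, leaving out each array, and an estimated correlation in camera. Alternatives chosen after seeing the data were the 3'/5' ratio of 3 control transcripts as a term, leaving out the 2 arrays with the highest ratio, and the block combined with that term, with another scaling or with arrays left out. The line over both treatments had 4 residual degrees of freedom, and 3 with the block. The other comparisons had 3, and 2 with the block. The ratio beside the block leaves fewer still, so calls from those fits rest on very little residual information.

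The tests were checked on simulated data of the 10218 probe sets, with the replicate shift of each probe set added alike to all replicate 2 arrays. Without the block, the fit recovered 59.7% of genes changed by log2 1 and 94.0% of those changed by log2 2 for the line over both treatments. For the line without dexamethasone these shares were 8.96% and 71.6%. For dexamethasone in the wild type they were 14.9% and 85.1%, for dexamethasone in the line 0% and 50.7%, and for the difference of the responses 0% and 16.4%. With the block the same shares were 85.1% and 100% for the line over both treatments, 80.6% and 100% for the line without dexamethasone, 86.6% and 100% for dexamethasone in the wild type, 43.3% and 100% for dexamethasone in the line, and 10.4% and 86.6% for the difference of the responses. The blocked fits called 8 to 10 unchanged genes per comparison and the others 0 to 1. The simulated shifts follow the model of the blocked fit exactly. In the real arrays the replicate deviations correlated only at 0.472 to 0.826, so the shares with the block may overstate what was recoverable here. The line with dexamethasone was not simulated. In a simulation of the difference of the responses without replicate shifts, a list of 15 genes shifted by log2 1 was called and 0 of 200 unshifted lists were. The simulated genes varied independently of each other. This check therefore cannot show how often lists of correlated genes are called falsely.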

Results

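The series addressed the nitrate response pathway in Arabidopsis roots. It used a transgenic line in the C24 background in which the MADS-box transcription factor ANR1, fused to the steroid-binding domain of the rat glucocorticoid receptor, is strongly expressed. Such a fusion is held outside the nucleus until a steroid such as dexamethasone is added. The labels describe plants starved of nitrogen for 2 days and transferred, after 9 days, for 1 h to 0 or 1 µM dexamethasone. The ecotype of the wild type is labelled as a control, so a difference in background between the line and the wild type was not separated from the transgene. The scaled signals had medians of 36.6 to 41.8 per array. No 2 arrays held equal signals for more than 1.60% of probe sets.

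The arrays grouped by replicate number before they grouped by genotype or treatment. Correlations of log2 signals ran from 0.959 to 0.988 between arrays of the same replicate number and from 0.912 to 0.962 between different numbers, while arrays of the same group correlated at 0.914 to 0.955. Replicate was therefore set beside the results below. RNA quality also differed between arrays. The 3'/5' signal ratio of actin was 0.251 to 0.528 in the replicate 1 arrays, 0.346 in the untreated wild type of replicate 2 and 0.388 in the treated line. It was 0.876 in the treated wild type of replicate 2 and 1.59 in the untreated line of replicate 2. The GAPDH ratio was 1.05 to 1.12 in replicate 1 and 1.18 to 1.55 in replicate 2. The ubiquitin ratio was 1.25 to 1.44 in replicate 1 and 1.48 to 2.19 in replicate 2. For GAPDH and ubiquitin the 3'/5' ratio was therefore confounded with the replicate number.

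The first comparison asked what distinguished the line from the wild type irrespective of dexamethasone. Probe set 263295_at was bright in each of the 3 line arrays and dim in each of the 4 wild type arrays, with a mean signal of 651 ± 327 (SD, n = 3) against 14.3 ± 6.43 (SD, n = 4). Its log2 difference was 4.34 ± 0.38 (SE), 5.20 within replicate 1 and 3.91 within replicate 2. Because the wild type signal was dim, the size depended on the number added before the log, and over all alternatives it ran from 3.09 with 64 added to 5.33 with 1 added. AT4G22450 had a mean signal of 61.9 ± 14.4 (SD, n = 3) in the line and 161 ± 7.10 (SD, n = 4) in the wild type, a log2 difference of -1.19 ± 0.15 (SE), with -1.61 within replicate 1 and -0.99 within replicate 2. Its probe set ends in _s_at. Probe set 257722_at had signals of 128 ± 18.7 (SD, n = 3) and 239 ± 55.2 (SD, n = 4), a log2 difference of -0.81. AT2G15560 had a log2 difference of -1.01 ± 0.47 (SE), with -1.74 within replicate 1 and -0.20 within replicate 2.

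By limma, 0 of the 10218 probe sets passed the threshold in this comparison, and 55 had an unadjusted p under 0.05, where 511 would be expected with no effect. The adjusted p was 0.0527 for 263295_at, 0.423 for AT4G22450 and 1.00 for 257722_at and AT2G15560. With the replicate block 1 probe set passed, 263295_at, at a log2 difference of 4.41 ± 0.35 (SE) and an adjusted p of 0.0134, and 163 had an unadjusted p under 0.05. AT4G22450 (-1.21) and 257722_at (-0.90) passed as well when the block and the 3'/5' ratio were both terms, a fit with fewer residual degrees of freedom. Probe set 263295_at also passed without the untreated line of replicate 2 (4.80, adjusted p 0.000468), and over all alternatives its adjusted p ranged from 4.0e-09 to 1. None of the 20 gene lists passed with or without the block (lowest camera adjusted p 0.244 and 0.715).

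**Figure D1:**
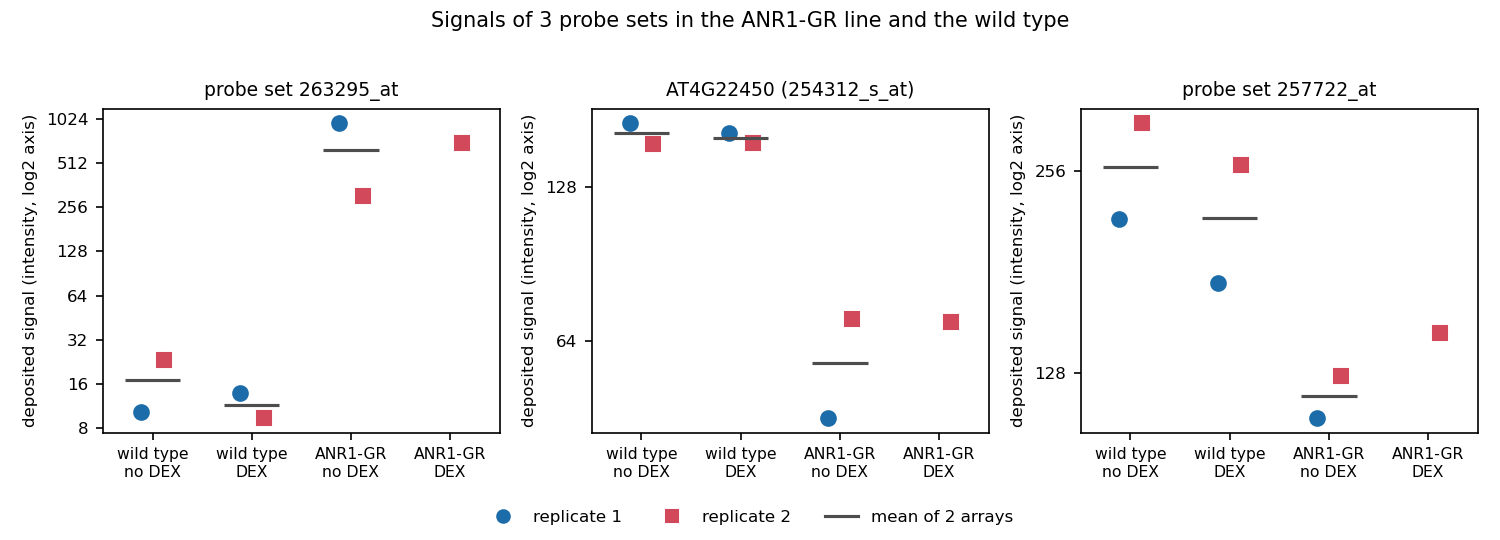
Deposited signal (intensity, log2 axis) of probe set 263295_at, AT4G22450 and probe set 257722_at in each array by group, with circles for replicate 1, squares for replicate 2 and a line at the mean where a group has 2 arrays. The 3 line arrays lie at 303.0 to 951 for 263295_at, above all 4 wild type arrays, and below all 4 wild type arrays in the other panels.

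Without dexamethasone, the line was compared with the wild type before nuclear entry of the fusion had been induced. The autophagy genes rose as a list in the line. All 10 measured members had positive differences, with a mean log2 of 0.20 and a camera adjusted p of 0.0352 (adjusted p = 0.908 with an estimated correlation). Members of the ATG8 family, whose proteins coat the autophagosome, were among them, with log2 differences of 0.19 ± 0.16 (SE) for ATG8F, 0.32 ± 0.27 for ATG8G, 0.24 ± 0.21 for APG8A and 0.26 ± 0.29 for ATG8H, and none passed alone. Without the untreated line array of replicate 2, which had the highest 3'/5' ratio, the mean of the list was -0.015. The call was also lost without the untreated wild type of replicate 1 (0.17) or of replicate 2 (0.24). ATG8H was -0.16 within replicate 1 and 0.69 within replicate 2.

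With the replicate block, the autophagy list kept its mean of 0.20 (camera adjusted p 0.00623), and the chloroplast-encoded genes fell, with 16 of 21 members negative and a mean of -0.22 (camera adjusted p 0.00623). For both lists the adjusted p = 0.808 with an estimated correlation. With the block and 1 array left out, the autophagy list no longer passed without the untreated line of replicate 2 (0.12) or the untreated wild type of replicate 2 (0.0080), and stood at 0.40 without the untreated wild type of replicate 1. The chloroplast list no longer passed without the untreated line of replicate 1 (-0.19) or the untreated wild type of replicate 2 (-0.060), and stood at -0.38 without the untreated wild type of replicate 1. With the 3'/5' ratio beside the block, the autophagy mean was 0.11 and no longer passed. No single probe set passed by limma with or without the block, and 42 and 383 had an unadjusted p under 0.05. The log2 difference of 263295_at was 4.10 ± 0.51 (SE), with 5.20 within replicate 1 and 3.01 within replicate 2, and it passed without the untreated line of replicate 2 (4.90, with an adjusted p of 0.0360 in a range from 2.3e-08 to 1). The difference of AT4G22450 was -1.29 ± 0.21. Probe set 257722_at stood at -1.03 ± 0.26 and AT2G15560 at -1.04 ± 0.66. The first 2 passed with the block and the 3'/5' ratio together (-1.43 and -0.98).

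Dexamethasone in the wild type served as the control for effects of the steroid. The untreated plants were transferred too, so this comparison does not measure an effect of the transfer. No probe set differed by 2-fold or more, and the largest log2 difference in size was 0.94. By limma 0 probe sets passed with or without the block, and 19 and 116 had an unadjusted p under 0.05. None of the 20 gene lists passed, the lowest camera adjusted p being 0.649 without and 0.237 with the block. The list means lay between -0.14 and 0.10 on the log2 scale.

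Dexamethasone in the line addressed the effect of inducing the fusion protein. The CYP71B cytochromes P450, a family of oxidases of specialised metabolism, fell as a list, with all 7 measured members negative, a mean log2 of -0.24 and a camera adjusted p of 0.00637 (adjusted p = 0.793 with an estimated correlation). The log2 difference was -0.39 ± 0.19 (SE) for CYP71B26, -0.33 ± 0.19 for CYP71B28, -0.26 ± 0.24 for CYP71B34 and -0.26 ± 0.32 for CYP71B29, none past the threshold alone. The list lost its call with the 3'/5' ratio as a term (-0.19), without the untreated line of replicate 2 (-0.17) and without the filter on dim probe sets (-0.14).

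Of the 18 probe sets with a log2 difference of at least 1 in size, the 5 genes with the smallest p among positive ones were ATSIK, a protein kinase, at 1.06 ± 0.35 (SE), AT4G28300 at 1.00 ± 0.36, AT3G54580, an extensin-like protein, at 1.01 ± 0.67, AT1G68490 at 1.14 ± 0.92 and AT3G28320 at 1.17 ± 1.35. In the other direction AT1G70880 stood at -1.29 ± 0.25, with a signal of 23.6 in the treated line against 81.2 ± 2.62 (SD, n = 2) in the untreated line. Within replicate 2, which holds the only treated line array, the difference was 1.07 for ATSIK, -1.27 for AT1G70880, 0.062 for AT3G28320 and 2.32 for AT1G68490, which turned to -0.050 without the untreated line of replicate 2. By limma 0 probe sets passed with or without the block, and 55 and 604 had an unadjusted p under 0.05.

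With the replicate block, 5 lists passed in this comparison. The chloroplast-encoded genes rose, with 19 of 21 members positive and a mean of 0.85 (camera adjusted p 2.8e-14), while without the block the mean was -0.0088. UDP-glycosyltransferases rose by 0.25 (0.0428), CYP71B genes fell by 0.32 (0.00121), autophagy genes fell by 0.34 (0.000548) and the cold, drought and dehydration genes fell by 0.20 (0.0175). For each of the 5 the adjusted p = 0.638 with an estimated correlation. With the block and 1 array left out, the chloroplast list (0.79 to 0.91), the CYP71B list (-0.34 to -0.30) and the autophagy list (-0.41 to -0.23) passed in each of the 6 fits. None of these fits leaves out the only treated line array, on which the comparison rests. Leaving out either array of a wild type group gave the same list mean, so the fits are not separate checks. The UDP-glycosyltransferases (0.070) and the cold and drought genes (-0.091) no longer passed without the untreated line of replicate 2, the array with the actin ratio of 1.59. With the 3'/5' ratio beside the block, the UDP-glycosyltransferases (0.039), the cold and drought genes (-0.048) and the autophagy genes (-0.12) no longer passed, whereas the chloroplast-encoded genes (0.72) and the CYP71B genes (-0.33) did. The first 2 also lost their calls with the block and quantile normalization (0.22 and -0.13). The direction of the chloroplast list depended on the block, for with the 3'/5' ratio as the only added term it passed as lower (-0.57). Without the block, this contrast sets 1 replicate 2 array against arrays of both replicates. Its value then carries part of the difference between the replicates. Within replicate 2 the mean log2 level of the list was 6.72 in the treated line and 5.88 in the untreated line.

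The response of the line minus that of the wild type is the effect of induction beyond dexamethasone itself. The CYP71B genes fell as a list, with 7 of 7 members negative, a mean of -0.34 and a camera adjusted p of 0.00472 (adjusted p = 0.818 with an estimated correlation). CYP71B28 stood at -0.44 ± 0.24 (SE), CYP71B26 at -0.43 ± 0.24, CYP71B34 at -0.30 ± 0.31 and CYP71B6 at -0.25 ± 0.26, none past the threshold alone. The call was lost without the untreated line of replicate 2 (-0.27), the untreated wild type of replicate 1 (-0.26) or the treated wild type of replicate 2 (-0.24), and without the filter on dim probe sets (-0.13). The genes with the smallest p among positive differences of at least 1 were AT5G25270 (2.64-fold) and AT5G11420 (2.15-fold), AT4G28300 at a log2 value of 1.47 ± 0.47, ATSIK at 1.25 ± 0.45 and AT4G17520 at 1.00 ± 0.37. Among negative ones they were AT1G70880 at -1.50 ± 0.33, AT3G24480, a leucine-rich repeat extensin, at -1.46 ± 0.33 and AT1G04985 at -1.15 ± 0.33. Within replicate 2 all 8 kept their sign, from -1.81 for AT1G70880 to 2.23 for AT4G28300. These genes were picked from the same arrays, and replicate 2 holds the only treated line array, so this is not a separate check.

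By limma 0 probe sets passed for the difference of the responses with or without the block, and 75 and 723 had an unadjusted p under 0.05. With the block the chloroplast-encoded genes rose (mean 0.79, 19 of 21 members positive, camera adjusted p 3.0e-08), where the mean without it was -0.073. The CYP71B genes fell by 0.42 (0.00135) and the autophagy genes fell by 0.43, with 10 of 10 members negative (0.00128). For these 3 lists the adjusted p = 0.680 with an estimated correlation. With the block and 1 array left out, the chloroplast list (0.54 to 1.00) and the CYP71B list (-0.44 to -0.39) passed in each of the 6 fits, all of which keep the only treated line array. The autophagy list no longer passed without the treated wild type of replicate 2 (-0.27), and stood at -0.69 without the untreated wild type of replicate 1. With the 3'/5' ratio beside the block, the chloroplast-encoded genes (0.64) and the CYP71B genes (-0.43) passed and the autophagy genes (-0.18) did not. The arrays with the highest 3'/5' ratios were the untreated line and the treated wild type of replicate 2. With the block and without both, which leaves no test, the mean was -0.42 for CYP71B genes, 0.094 for autophagy genes and 0.36 for chloroplast-encoded genes. The chloroplast list passed as lower without the block, at -0.81 with the 3'/5' ratio as a term and -1.90 without both arrays, where replicate 2 is set against replicate 1.

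With dexamethasone in both, AT5G25270 was higher in the line by 1.03 ± 0.22 (SE) on the log2 scale, and AT1G70880 stood at -1.08 ± 0.25 and AT4G22450 at -1.03 ± 0.26. AT3G28320 (1.27), AT5G04120 (1.83), AT4G11210, a dirigent protein (1.19), the beta-glucosidase gene BGLU28 (1.14) and the extensin-like AT1G26250 (-1.06) also had large differences, but within replicate 2 these lay between -0.057 and 0.23. By limma 0 probe sets passed with or without the block, and 41 and 388 had an unadjusted p under 0.05. Without the block 0 lists passed (lowest camera adjusted p 0.105).

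With the block the chloroplast-encoded genes rose in the treated line (mean 0.57, 19 of 21 positive, camera adjusted p 2.3e-09), whereas the mean without it was -0.29. The CYP71B genes fell by 0.26 (0.0085) and the autophagy genes fell by 0.23 (0.0182), with 6 of 7 and 9 of 10 members negative. For all 3 lists the adjusted p = 0.785 with an estimated correlation. Without the block the means of the CYP71B and autophagy genes were -0.18 and -0.059. Leaving out the treated wild type of replicate 2 in the fit with the block, the CYP71B (-0.24) and autophagy (-0.069) lists no longer passed and the chloroplast list (0.32) did. With the 3'/5' ratio beside the block, the autophagy genes (-0.064) no longer passed, and the CYP71B (-0.27) and chloroplast-encoded genes (0.47) did. The autophagy call was also lost with the block and quantile normalization (-0.20). With the 3'/5' ratio as the only added term the chloroplast list passed as lower (-0.55).

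**Figure D2:**
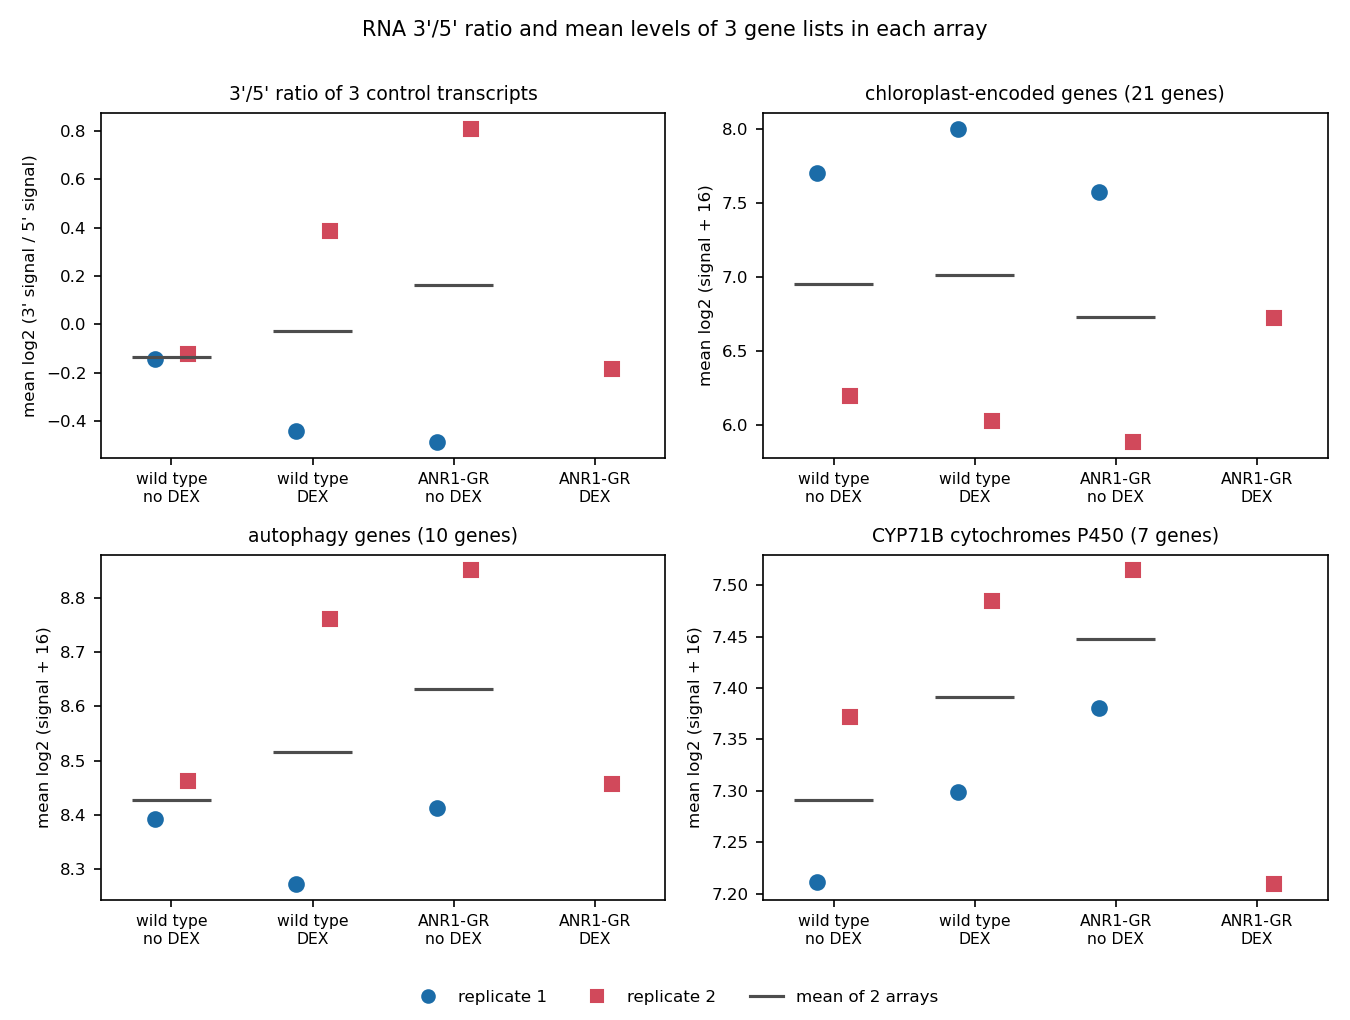
Mean log2 3'/5' ratio of 3 control transcripts and mean log2(signal + 16) of the chloroplast-encoded, autophagy and CYP71B gene lists in each array by group, with circles for replicate 1, squares for replicate 2 and a line at the mean where a group has 2 arrays. The chloroplast-encoded genes lie at 7.57 to 8.00 in replicate 1 and at 5.88 to 6.72 in replicate 2, and the untreated line of replicate 2 has the highest 3'/5' ratio (0.81).

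Genes of the nitrate pathway and relatives of ANR1 were fixed as lists in advance. Among MADS-box genes, dexamethasone in the line gave log2 differences of -0.21 ± 0.23 (SE) for AGL16, -0.23 ± 0.33 for AGL21 and 0.38 ± 0.20 for AGL18. Of the nitrate transport list the transporter gene AT2G26690 was measured, at 0.082 ± 0.34, and of the nitrate signalling regulators AT1G25550 at -0.14 ± 0.26 and AT1G68670 at 0.14 ± 0.22. None of the 19 measured genes of all fixed lists passed in any of the 6 comparisons by limma, and 0 passed adjusted over the list alone, with or without the block. Without the block 0 had an unadjusted p under 0.05. That count was not taken with the block.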

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

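The tests of the 3'/5' ratio as a term, without both arrays of highest ratio and with the block and arrays left out were chosen only after the data had been seen, whereas the test without the untreated line of replicate 2 was planned.

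Control probe sets outside the comparisons stood apart in replicate 2. The actin 3'/5' ratio was 1.59 in the untreated line and 0.876 in the treated wild type, against at most 0.528 in the other 5 arrays. The 25S rRNA control signal reached 52.1 in the treated line and 25.5 to 44.3 in the other replicate 2 arrays, against 5.20 to 10.5 in replicate 1. No group had enough arrays for a test of single outlying samples.

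The difference of the dexamethasone responses between line and wild type was tested for each list. With the replicate block the mean was 0.79 for the chloroplast-encoded genes, -0.42 for the CYP71B genes and -0.43 for the autophagy genes. Without the block only the CYP71B genes passed among the 20 lists, with a mean of -0.34.

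For the CYP71B genes, leaving out the untreated line of replicate 2 gave -0.27 ± 0.07 (SE over members, n = 7) against -0.34 ± 0.04 with all arrays, and with the block -0.44 ± 0.07, which argues against that array as the whole cause, although without the block the list no longer passed (adjusted p 0.0903) with fewer arrays. With the 3'/5' ratio as a term the mean was also -0.27 ± 0.06, and the list lost its call (adjusted p 0.0894); over all alternatives its adjusted p ran from 0.000246 to 0.818. The bound, at least 0.5 of the mean kept, was met by that value. It was written before this test was run, but the test itself was chosen after the data had been seen. The bound was also met with the block and the 3'/5' ratio together (-0.43 ± 0.11). The same was so with the block without both arrays of highest ratio (-0.42 ± 0.19, no test), against -0.42 ± 0.06 with the block. These values do not settle RNA integrity as a cause. The block and the ratio together leave few residual degrees of freedom. Without both arrays, the replicate shift rests on the untreated wild type alone, the only group left with arrays of both replicates. Both arrays of highest ratio also enter the contrast with the same sign. Each SE here is a spread over genes of the same arrays, and every value rests on the only treated line array. The spread between arrays is not measured, so the argument on the untreated line of replicate 2 does not reach beyond these arrays. Without both arrays and without the block the mean was -0.18 ± 0.11, a value that sets replicate 2 against replicate 1. The verdict on RNA integrity was set to open when that value was seen, and was set back after the values with the block had been added. For the reasons above it is left open here. Shared signal stays open, since 0 of the 7 probe sets end in _s_at or _x_at and leaving such probe sets out changed nothing (-0.34). An effect of the induced fusion protein, which the design names, may also underlie the pattern and stays untested with 1 treated line array.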

How the results depend on the processing

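The tests with the 3'/5' ratio as a term, without both arrays of highest ratio and with the block combined with another choice were chosen only after the data had been seen, as was every test of replicate 2 against replicate 1.

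Of the values for single genes and gene lists under the alternatives, 1161 kept direction and side of the threshold, 95 passed where they had not, 22 no longer passed, 2 moved without a test and 78 turned direction. These genes are the ones the text names, a restriction made after a wider tally had been seen; over all 19 measured members of the fixed lists in the 6 comparisons, 288 of 2358 values turned direction and 0 crossed the threshold. The cause was not tested except where fewer arrays or genes explain it. For the line over both treatments, the count of calls was 0, and it was 1 with 1 added before the log, arrays centred on the median, the stricter filter on dim probe sets, the replicate block (alone, with quantile normalization or with arrays centred on the median), the 3'/5' ratio as a term, and without both arrays of highest 3'/5' ratio; leaving out each array gave 0 to 1. Each of these calls was 263295_at. For the line without dexamethasone, where 0 passed, the 3'/5' ratio as a term and leaving out both arrays of highest 3'/5' ratio gave 1, and leaving out each array gave 0 to 1. With dexamethasone, leaving out both arrays gave 1, leaving out each array 0 to 1. The replicate block and 3'/5' ratio as terms gave 5, 5 and 1 in these 3 comparisons, the first 2 with AT4G22450 and 257722_at beside 263295_at. The call on leaving out 1 array came without the untreated line of replicate 2. The other 3 comparisons had 0 calls in every alternative. For replicate 2 against replicate 1, 1386 passed with the 3'/5' ratio as a term, and leaving out each array gave 1029 to 2642.

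The replicate block turned the chloroplast-encoded genes to 0.85 for dexamethasone in the line, 0.79 for the difference of responses and 0.57 for the line with dexamethasone. The same 3 values were 0.72, 0.64 and 0.47 with the 3'/5' ratio added, 0.79, 0.71 and 0.51 with arrays centred on the median, and 0.81, 0.71 and 0.50 with quantile normalization. The block turned AT1G26250 to 0.15 (0.090 centred, 0.074 quantile), and block with centring turned AT3G28320 to -0.0011 and BGLU28 to -0.020. Block and 3'/5' ratio together turned AT3G54580 to -0.49, AT1G68670 to -0.081, AGL21 to 0.38 and CYP71B34 to 0.027 (dexamethasone in the line) and 0.018 (difference of responses). The replicate block changed no other call than those given beside the results. With 1 added before the log, the chloroplast-encoded genes were 0.069 for dexamethasone in the line and 0.026 for the difference of responses. The 3'/5' ratio as a term, without the block, turned them to 0.26 without dexamethasone, not past the threshold. It gave them calls opposite to those with the block, at -0.57 for dexamethasone in the line, -0.81 for the difference of responses and -0.55 with dexamethasone. It turned the UDP-glycosyltransferases to -0.032 and the autophagy genes with dexamethasone to 0.0055.

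Without both arrays of highest 3'/5' ratio and without the block, the chloroplast-encoded genes passed at 0.62 for the line without dexamethasone, -0.85 for dexamethasone in the line, -1.90 for the difference of responses and -1.28 with dexamethasone, each opposite to the block. The line without dexamethasone had -0.015 for autophagy genes and -0.11 for ATG8H. Dexamethasone in the line had -0.050 for AT1G68490, -0.14 for UDP-glycosyltransferases, 0.045 for cold and drought genes and 0.044 for autophagy genes. The autophagy genes were at 0.20 for the difference of responses and 0.18 with dexamethasone.

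With the block and without both of these arrays, which leaves no test, dexamethasone in the line had 0.66 for chloroplast-encoded genes, -0.044 for UDP-glycosyltransferases and 0.015 for cold and drought genes. The chloroplast-encoded and autophagy genes were at 0.36 and 0.094 for the difference of responses, and at 0.23 and 0.11 with dexamethasone.

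Without the block, leaving out arrays sets replicate 2 partly or wholly against replicate 1, so that such values carry the difference between the replicates. The same holds in part with all arrays for the comparisons that need the treated line, whose only array is in replicate 2. Leaving out each array in turn, the ranges without dexamethasone were -1.06 to 0.62 for chloroplast-encoded genes, -0.015 to 0.42 for autophagy genes and -0.11 to 0.64 for ATG8H. For dexamethasone in the line they were -0.85 to 0.83 for chloroplast-encoded genes, -0.14 to 0.34 for UDP-glycosyltransferases, -0.26 to 0.045 for cold and drought genes, -0.39 to 0.044 for autophagy genes, -0.050 to 2.32 for AT1G68490 and -0.24 to 0.40 for AT2G26690. For the difference of responses the chloroplast-encoded genes ran from -1.06 to 0.91. With dexamethasone the ranges were -1.28 to 0.69 for chloroplast-encoded genes, -0.30 to 0.18 for autophagy genes, -0.057 to 3.72 for AT5G04120 and -2.35 to 0.23 for AT1G26250. With the block, leaving out each array gave 0.54 to 1.00 for chloroplast-encoded genes in the difference of responses and -0.41 to -0.23 for autophagy genes with dexamethasone in the line. The autophagy call without dexamethasone was lost under quantile normalization (0.19), arrays centred on the median (0.23), no filter (0.20) and the 3'/5' ratio as a term (0.082).

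Leaving out the only treated line array was not run for the 3 comparisons that need it, nor were the alternatives planned for ANR1. The lists of the nuclear genes of chloroplast function and of the CYP71B genes had too few genes under the stricter filter. Signals near the scanner background limit what dim probe sets show.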

Other observations

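The comparison of the replicates, its lists and the tests of its explanations were chosen only after the data had been seen, as were its splits of the arrays and the test on 263295_at. The splits for the line against the wild type were planned.

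The genes of the chloroplast were lower together in replicate 2 (4 arrays) than in replicate 1 (3 arrays), across genotypes and treatments. Of 21 measured chloroplast-encoded genes, 19 passed as lower and 0 as higher, with a mean log2 difference of -1.55 (camera adjusted p 1.0e-13, and adjusted p = 0.736 with an estimated correlation). The ATP synthase subunit gene atpB had a signal of 68.4 ± 51.0 (SD, n = 4) in replicate 2 and 487.5 ± 75.2 (SD, n = 3) in replicate 1, a log2 difference of -2.78, and atpE, matK and petB stood at -2.65, -2.23 and -2.06. Among 7 nuclear genes of chloroplast function 5 passed as lower, with a mean of -0.49 (camera adjusted p 0.00822, and adjusted p = 0.748 with an estimated correlation). They included RCA, the activase of Rubisco, at -0.79, PSBY at -0.78 and LHCB4.1, a light-harvesting protein gene, at -0.45.

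Other genes also differed between the replicates. The extensin-like AT1G26250 had a signal of 42.6 ± 13.7 (SD, n = 4) in replicate 2 and 288 ± 27.6 (SD, n = 3) in replicate 1. The log2 difference was -2.04 for ccb382, which is in neither chloroplast list, so falls of that size were not confined to those lists. It was -1.86 for the monolignol glycosyltransferase gene UGT72E1 and -1.22 for GH3.3, whose enzyme conjugates auxin to amino acids. Genes higher in replicate 2 included AT5G04120 (3.29), the berberine bridge enzyme-like AT1G26390 (2.47), the dirigent protein genes AT4G11190 (2.35) and AT4G11210 (2.19), the sulphur-starvation gene BGLU28 (2.18), the glutathione transferase GSTU28 (1.19) and the chalcone isomerase-like CHIL (1.01). In all, 2467 of 10218 probe sets passed by limma (24.1%), 1173 higher and 1294 lower in replicate 2. Without the 2 arrays of highest 3'/5' ratio 1820 passed, of which 1550 were shared with the 2467. Without the treated wild type of replicate 1 the number was 1029.

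Of the 35 splits of the 7 arrays into 3 and 4, 1 gave as many calls as the replicate numbers, the split by replicate itself, and the highest other count was 707. Because this comparison was added after the arrays had been seen to group by replicate number, that count restates the grouping and does not settle whether chance is excluded. What differed between the replicates (growth, harvest, RNA or hybridisation) is not given in the sources used here. The sample titles carry a code that is shared within each replicate and differs between them, without saying what it marks.

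RNA integrity stays open as a cause of the lower chloroplast-encoded genes. With the mean 3'/5' ratio of the 3 control transcripts as a term, the list kept -1.21 ± 0.11 (SE over members, n = 21). By that mean, the 2 replicate 2 arrays with the lowest ratios lay near replicate 1. The GAPDH and ubiquitin ratios, however, were higher in each replicate 2 array (1.18 to 1.55 and 1.48 to 2.19) than in any replicate 1 array (at most 1.12 and 1.44). By these ratios no replicate 2 array matched replicate 1, so neither the term nor these arrays can argue against RNA integrity. The treated line, whose mean log2 ratio of -0.19 lay within the range of replicate 1, was lower than the replicate 1 mean by a log2 difference of -1.04, and the untreated wild type by -1.56. The criterion first written asked that both arrays lie within the range of replicate 1; the untreated wild type lay just above it (-0.12 against -0.15), which left that test undecided, and the criterion was reset after the values were seen. Another difference in RNA preparation stays open, because the 25S rRNA control signal was 25.5 to 52.1 in replicate 2, with 52.1 and 44.3 in these 2 arrays, against 5.20 to 10.5 in replicate 1, a gap of 15 that cannot be told apart from anything else that differed between the replicates. A lower share of green tissue in replicate 2 may account for part of the difference, because the nuclear genes of chloroplast function were lower too (-0.49 ± 0.11, SE over members, n = 7). All 7 were measured in these roots, and the smaller size of their difference leaves the rest of the -1.55 open. No biological explanation was tested; 3 of the 4 groups had an array in each replicate and the treated line only in replicate 2.

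For the line against the wild type over both treatments, the real split gave 0 calls, so that 34 of 34 splits that could be fitted necessarily gave at least as many, and this test says nothing about chance. The highest other count, 1950, came from the split by replicate number, and 3 splits gave any call, which points to a structure of the samples. The real split holds 1 replicate 1 array among its 3, and the 16 other fitted splits of that kind gave 0 calls. With the block 2 of 33 splits gave as many calls as the real split (1), so chance cannot be excluded there, and the highest other count was 78, from the untreated line of replicate 2 with both treated wild type arrays, which include both arrays of highest 3'/5' ratio.

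For probe set 263295_at, the lowest line array lay above the highest wild type array by 3.01 on the log2 scale. In these arrays its difference therefore did not come from a single array. The probe set was picked for its small p in this same comparison, so the separation of its arrays is not independent support. The gene it reads is unnamed in the annotation used here.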
